A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

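RNA of 3 strains was compared on 4 two-colour slides. Per the labels, total RNA of cells kept in 0.6 mol/L NaCl for 45 min was purified on columns, amplified linearly by the Eberwine method, turned into cDNA and labelled with Cy5 or Cy3 by Klenow enzyme, and BF2B or BF2S was hybridised with BF2 on oligonucleotide arrays. Per the file headers, the scanner files hold the intensity of each spot and of its local background at 635 nm (Cy5) and 532 nm (Cy3). The deposited value table holds log2 ratios. Checked against the scanner files, its values were found to be log2 of strain over BF2 from the background-subtracted medians of the first of a probe's 3 spots, with the sign turned in replicate 2 and no centring. Between 62.7% and 69.7% of values matched within 0.001, the correlation was at least 0.9998, and the medians of its 4 columns were 0.20, -0.29, 0.23 and -0.80. Scanner, extraction software and the labelled strand are not given in the sources used here, so overlapping genes on opposite strands were not separated.

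Ratios were recomputed from the spot medians with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, each slide was corrected by loess fitted to gene spots, the 3 spots of a probe were averaged, and ratios were turned to strain over BF2 by the dyes in the labels. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of 6388 gene probes, 5849 were matched to the gene table by systematic name and 539 were not, and these kept their systematic name. A channel was above background when at least 2 of 3 spots exceeded the local background mean plus 2 SD. Where the dimmer channel of a called gene was not above background on either slide, a bound on the fold is given in place of the value, and this bound rests on the loess correction. Where it was above background on only 1 slide, the plain value is printed. Where spots reached the limit of 65535, the value is printed together with that fact, since loess keeps it from being a bound. No bounds were computed for BF2S against BF2B.

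Both slides of a comparison are a dye swap of the same RNA pair and counted as 1 replicate, so no test was made. A gene was called when it differed by over 2-fold in the same direction on both slides and was above background in at least 1 channel on both. BF2S was compared with BF2B by the difference of their log2 ratios to BF2, between slides of the same dye orientation. For 35 gene lists the median log2 ratio was placed among medians of 10000 random lists of the same size drawn from 10 intensity bins. A list lay outside the random range below percentile 2.5 or above 97.5. The rule for names took, for each comparison, the 12 called genes with the largest increase and decrease, BDF1, BDF2, SIR2 and the marker genes, and up to 4 called members of each list, or 2 members where none was called. The text leaves out some list members not above background and, for the sample labelled BF2S, a part of the others.

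The rules for calls, comparisons, lists and names were chosen before the data were examined. The plan was also to leave out spots marked as bad. This was not done in the values reported: the only mark in the files, -100, is not explained there and was set on 54.6%, 0%, 32.0% and 67.3% of the gene spots of the 4 slides. Keeping those spots was decided after the files were seen, and leaving them out was added as an alternative. A filter on genes above the 95th percentile of blank spots, and list medians with genes set at their bounds, were added after the data were seen too.

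The alternatives fixed beforehand were no background subtraction, an offset of 10, median centring in place of loess, scaling between slides, the deposited value table, the median of a probe's spots, no filter on dim genes, both channels above background, thresholds of 1.5-fold and 3-fold, the mean ratio alone, each slide alone, random lists without matching, and 5 or 20 in place of the 10 outermost open reading frames per chromosome arm. On arrays the signal over background limits precision. The share of gene spots above background on the BF2B slides was 77.0% and 74.9% in Cy5 and 42.8% and 44.9% in Cy3. On the BF2S slides it was 64.4% and 35.8% for BF2S and 75.4% and 93.6% for BF2. Tested on simulated data, the rule called 98.4% of genes changed by a log2 of 2.5 and 62.7% of those changed by 1.5 in BF2B. There was 1 wrong call among 4312 genes that were unchanged or, in a small part, shifted by 0.5. The simulation held technical noise only, with no difference between cultures.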

Results

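The series measured messenger RNA in 3 strains of the budding yeast Saccharomyces cerevisiae after salt treatment, 0.6 mol/L NaCl for 45 min. BF2 lacked BDF1 and carried the plasmids pYX242 and pRS316. BF2B lacked both BDF1 and BDF2 and carried a construct written BDF2 L together with pYX242. BF2S lacked the same pair of genes and carried BDF2 L together with a construct written SIR2 H in place of pYX242. What L and H stand for is not stated in the labels. BDF1 and BDF2 encode bromodomain proteins that bind acetylated histones, and SIR2 encodes an NAD-dependent histone deacetylase of silent chromatin. Each of BF2B and BF2S was hybridised against BF2 on 2 oligonucleotide array slides, of which the second had the dyes exchanged, so 4 slides were used. Both slides of a comparison held the same RNA pair and were treated as 1 replicate. No test against the spread between cultures was therefore possible, no p-values are given, and each SD printed below is the technical spread of 2 hybridisations. A gene was called higher or lower when it differed by over 2-fold in the same direction on both slides and was above background in at least 1 channel of each.

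Each slide held 23184 spots, among them 6388 gene probes with 3 spots each. The BF2B slides were clean. Their median gene signals lay between 463.75 and 667 brightness units above local background, and their blank spots had medians of 29 to 110 units. The BF2S slides were not. Blank spots on them had medians of 6049 and 5325 units in the BF2S channel, above 96.0% and 98.3% of the genes, and of 1709 and 1768 units in the BF2 channel. Across genes, which are not independent replicates, the BF2 signals of the BF2S slides correlated with those of the BF2B slides at a Pearson r of 0.868 to 0.914. The BF2S signals correlated with the BF2B signals at only 0.113 to 0.176, although the 2 BF2S hybridisations correlated with each other at 0.883 and with BF2 on the same slides at 0.405 to 0.482. For this reason the text speaks of the sample labelled BF2S.

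**Figure D1:**
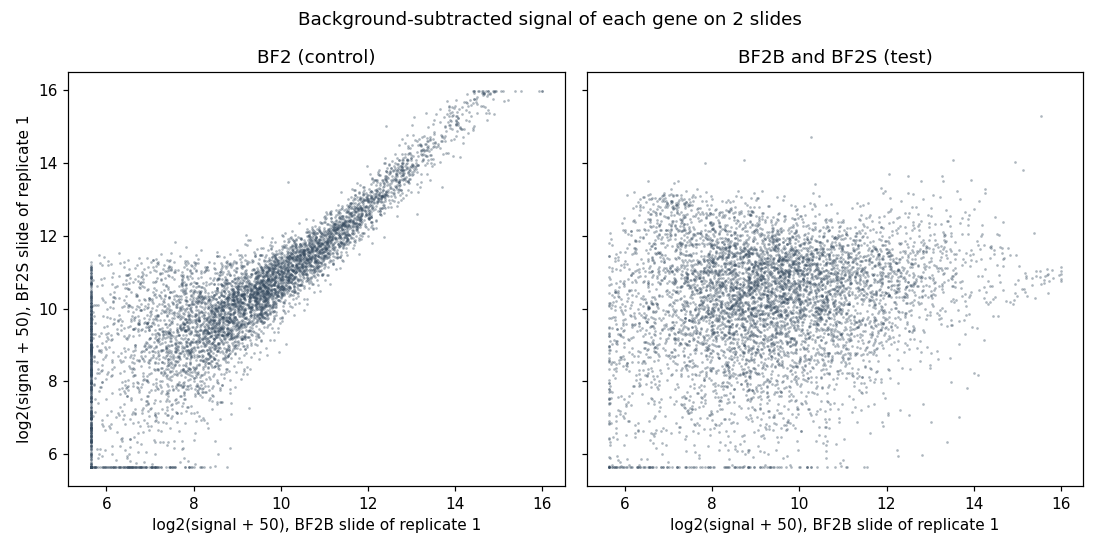
Each point is a gene, placed by its background-subtracted signal, as log2 of the signal plus 50, on the BF2B slide (horizontal) and the BF2S slide (vertical) of replicate 1. The BF2 signals (left) follow a diagonal, with r = 0.868 across genes, while the BF2B and BF2S signals (right) form a broad cloud, with r = 0.154.

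The manipulated genes were examined first. BDF1, deleted in every strain, was not above background in either channel of the BF2B slides. In the sample labelled BF2S, however, the BDF1 probe gave 1580 and 419.5 units beside 161.2 and 404.8 units in BF2, a log2 ratio of 1.64 ± 0.28 that met the rule for a higher gene. On the first slide only the BF2S signal was above background, and on the second only that of BF2, so the size of this ratio is uncertain. BDF2 was higher in BF2B than in BF2, with a log2 ratio of 1.61 ± 0.03 or 3.04-fold. In the sample labelled BF2S its log2 ratio was 0.65 ± 0.61, not called, and turned to -0.73 when the slides were centred on their median in place of the intensity-dependent loess correction. SIR2 was not above background in either channel of the BF2B slides. It met the rule for a higher gene in the sample labelled BF2S, with a log2 ratio of 1.51 ± 0.18, from signals of 1738 and 1320 units beside 274.8 and 706.7 units in BF2, the former of which was not above background. Both BF2S signals lay below the medians of the blank spots in that channel, 6049 and 5325 units. The deleted BDF1 had a similar ratio there, so this value alone does not show expression from SIR2 H. LEU2, the marker gene of pYX242, was lower in BF2B, with a log2 ratio of -2.47 ± 0.20 from spots saturated in BF2 and of -2.31 under median centring, and URA3, the marker gene of pRS316, was lower in BF2B by a log2 ratio of -1.12 ± 0.08. The remaining marker genes HIS3, TRP1, LYS2, ADE2, MET17 and CAN1 were not called in BF2B, with CAN1 at -0.71 ± 0.29 and the others between -0.22 and 0.14.

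The comparison of BF2B with BF2 asked how transcripts under salt differ when BDF2 comes from the construct BDF2 L. INO1 (YJL153C), which makes the inositol precursor in the rate-limiting step of inositol synthesis, was 23.8-fold higher in BF2B, with a log2 ratio of 4.57 ± 0.02. PHO84 (YML123C), the high-affinity phosphate transporter, was 17.6-fold lower, at -4.14 ± 0.41. Genes of iron uptake, ergosterol synthesis and the G1/S transition lay higher in BF2B, whereas osmotic and general stress genes lay lower. In all, 139 of 4660 genes above background were called, 64 higher and 75 lower. Across these genes the log2 ratios of the 2 hybridisations correlated at r = 0.640, with a median SD of 0.19. The hybridisation error of a mean log2 ratio was 0.22 to 0.37 depending on intensity. It was pooled over the BF2B and BF2S slides and all gene probes, so it is not the error of the BF2B slides alone. A single gene exceeded 2-fold in opposite directions on the 2 slides, PSR1, which was picked out after its values were seen.

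**Figure D2:**
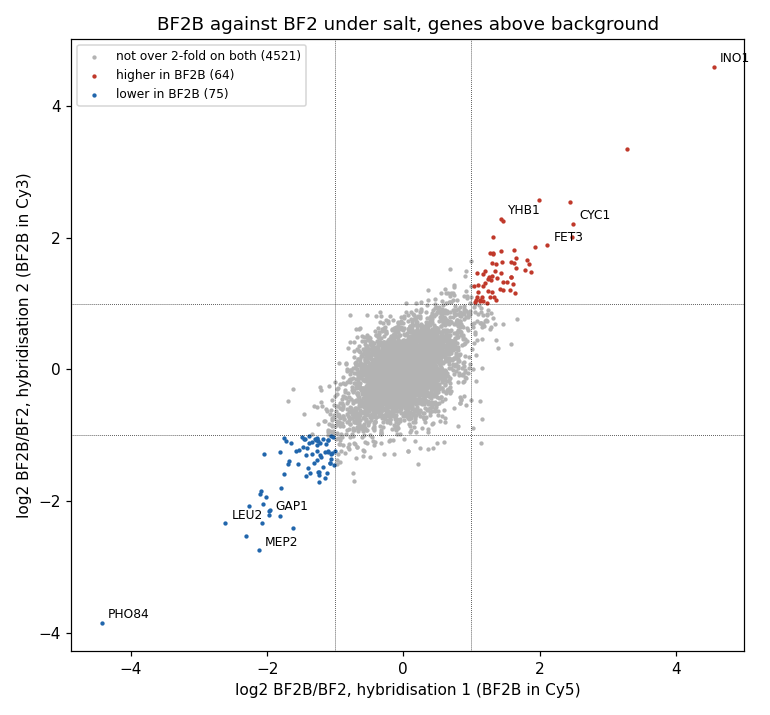
Each point is a gene above background, with its log2 ratio of BF2B to BF2 on the slide with BF2B in Cy5 (horizontal) and with BF2B in Cy3 (vertical), and dotted lines mark 2-fold. INO1 (mean 4.57) and PHO84 (mean -4.14) stand at the ends, with 64 genes called higher in red and 75 lower in blue.

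Behind INO1, the leading increases included genes of iron uptake, the cell wall and inositol transport. YEL073C, a subtelomeric open reading frame, was 5.65-fold higher, and CYC1, which encodes cytochrome c, reached a log2 ratio of 2.35 ± 0.20. SAM2, an S-adenosylmethionine synthetase, reached 2.24 ± 0.33. FET3 and FTR1, the oxidase and permease of high-affinity iron uptake, reached 2.00 ± 0.16 and 1.71 ± 0.13. The cell wall genes TIP1 and UTR2 reached 1.89 ± 0.06 and 1.85 ± 0.56, and the inositol transporter gene ITR1 1.72 ± 0.17. YKR075C stood at 1.73 ± 0.11. YGR067C and the flavohaemoglobin gene YHB1 were not above background in BF2 and were at least 2.43-fold and at least 1.87-fold higher.

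Several of the leading decreases belonged to nitrogen use. The ammonium permease gene MEP2 fell to -2.43 ± 0.44 and the general amino acid permease gene GAP1 to -2.09 ± 0.17, and DAL80, a repressor of nitrogen catabolic genes, was at least 2.40-fold lower. CMK1, a calmodulin-dependent kinase gene, stood at -2.20 ± 0.18, DET1 at -2.42 ± 0.15 and the vacuolar aminopeptidase gene APE1 at -2.05 ± 0.02. SHH3, a homologue of a succinate dehydrogenase subunit, stood at -2.01 ± 0.56, and its relative SHH4 was at least 3.13-fold lower. The chaperone gene SSA3 stood at -2.02 ± 0.29 and YOR186W at -2.06 ± 0.13.

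Of the 35 gene lists, 8 had medians below and 12 above the middle 95% of 10000 random lists of equal size and intensity, where 1.75 would lie outside by chance if lists were independent draws. Osmotic and general stress genes were among the lowest. The 31 Hog1-dependent osmotic response genes had a median log2 ratio of -0.69, below all random lists, with 0 higher, 4 lower and 27 not called. The 4 were PUT1 (-1.96 ± 0.17), HSP12 (-1.67 ± 0.12), the catalase gene CTT1 (-1.40 ± 0.24) and MSC1 (-1.25 ± 0.23). Of the Msn2/4 environmental stress genes, 9 were lower and 1 was higher, with 49 of the 59 above background not called, and the median was -0.50, again below all random lists. FMP45 (-1.53 ± 0.40) and HSP26 (-1.40 ± 0.22) were among the 9, together with HSP12, CTT1 and MSC1, which both lists hold. The Hog1 and Msn2/4 lists are therefore not separate evidence. The 1 higher gene was RIM4 (1.24 ± 0.10), named after its value was seen. The median of the heat shock proteins and chaperones was -0.28, with 0 higher, 2 lower (SSA3 and HSP26) and 36 not called. That of the oxidative stress defence genes was -0.24, with 0 higher, 4 lower and 30 not called, and besides CTT1 these were the peroxiredoxin gene TSA2 (-1.47 ± 0.14), the thioredoxin reductase gene TRR2 (-1.36 ± 0.08) and CTA1 (-1.03 ± 0.01).

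Phosphate and translation genes also lay low. The phosphate regulon had a median of -0.49, with 0 higher, 2 lower (PHO84 and VTC1, -1.15 ± 0.16) and 13 not called. Mitochondrial ribosomal proteins shifted as a group, with a median of -0.32, although 0 of the 65 members above background were called, and the farthest of them, MRPS9, stood at -0.78 ± 0.29 and MRP51 at -0.76 ± 0.05. Cytosolic ribosomal proteins had a median of -0.17, with 0 higher, 1 lower (RPL29, -1.25 ± 0.33) and 136 not called. Each of these 3 medians was below all random lists. The autophagy and cell death genes had a median of -0.14 at percentile 0.32, with 0 higher, 1 lower (ATG18, -1.15 ± 0.16) and 40 not called. The autophagy list entered the random range in the deposited value table, with the median of a gene's spots and with spots marked -100 in the files left out. With genes at their bounds its median was -0.08, for which no random lists were drawn.

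Iron, sterol and cell cycle lists lay high in BF2B. The iron regulon had a median of 0.38, above all random lists, with 4 higher, 0 lower and 18 not called, and FIT2 (1.35 ± 0.08) and FRE2 (1.04 ± 0.02) joined FET3 and FTR1. Ergosterol biosynthesis had a median of 0.33, above the random range of -0.15 to 0.14, with 2 higher (ERG5, 1.65 ± 0.20, and ERG3, 1.40 ± 0.34), 0 lower and 22 not called. The G1/S cell cycle genes had a median of 0.39, above all random lists, with 3 higher, 0 lower and 16 not called. These 3 were SVS1 (1.60 ± 0.08), the ribonucleotide reductase gene RNR1 (1.15 ± 0.16) and the replication protein gene RFA1 (1.13 ± 0.04). The G2/M and M/G1 genes had a median of 0.28, also above all random lists, with 0 of 31 called and CLN3 at 0.86 ± 0.23. CDC6 was not above background on both slides. The a-specific genes had a median of 0.69, above all random lists, over 8 members of which 1 was higher (the a-factor gene MFA2, 1.61 ± 0.01), 0 were lower and 5 were not called.

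Among lists of carbon and amino acid metabolism, glycolysis and fermentation had a median of 0.32 at percentile 99.9, although the 1 call was a decrease (PDC6, -1.53 ± 0.21) and 21 members were not called. Gcn4-controlled amino acid genes had a median of 0.19 at percentile 99.97, with 3 higher (LEU1, 1.39 ± 0.26, SNO1, 1.11 ± 0.15, and SNZ1, 1.09 ± 0.05), 0 lower and 52 not called. The respiratory chain list had a median of 0.15 at percentile 99.1, with 1 higher (CYC1), 1 lower (NDE2, -1.25 ± 0.27) and 40 not called. The proteasome list had a median of 0.16 at percentile 99.2, with 0 higher, 1 lower (RPN12, -1.03 ± 0.04) and 33 not called. RPN12 (YFR052W), RPL29 (YFR032C-A) and ATG18 (YFR021W), each the single decrease of its list, lie on chromosome VI by their systematic names. So do the lower CMK1 and HSP12 and the uncalled LPD1 and CDC14, while GSY1 on that chromosome stood at 0.81. This was seen after the values, and a shift of the chromosome was not tested. Methionine and sulfate genes had a median of 0.20 at percentile 99.5, with 2 higher (SAM2 and the transporter gene SAM3, 1.10 ± 0.09), 0 lower and 17 not called. Haploid-specific and pheromone response genes had a median of 0.16 at percentile 98.9, with 0 higher, 1 lower (RME1, -1.16 ± 0.15) and 9 not called. The proteasome, methionine and haploid-specific lists re-entered the random range in the deposited value table and on the slide with BF2B in Cy5 alone. The latter pair also did so on the other slide, and the haploid-specific list with the marked spots left out.

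The 320 subtelomeric open reading frames, the 10 outermost of each chromosome arm, had a median of 0.20, above all random lists, with 7 higher, 5 lower and 126 not called. ZRT1 (1.52 ± 0.34) and DLD3 (2.82-fold) were higher beside YEL073C, and AAD10 (-1.49 ± 0.08) was lower. Only 138 members were above background, and with every gene at its bound, or at 0 where no fold could be given, the median was 0.00. The same step brought the methionine and haploid-specific medians to 0.00, the G1/S median to 0.22 and the phosphate median to -0.32, and left the Hog1 median at -0.69. It can only move values towards 0, and no random lists were redrawn for it, so these medians have no percentile.

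The other 15 lists lay inside the random range. The list for the subtelomeric COS family, which took genes by the name COS alone, had a median of 0.15 with 1 higher and 8 not called. The 1 higher was COS111 (YBR203W, 1.27 ± 0.27), a member by name only, so its call does not speak for a subtelomeric family. The seripauperin and cell wall mannoprotein genes had a median of 0.02 with 1 higher (PAU20, 1.06) and 21 not called. Silent mating-type loci and silencing factors had a median of 0.02 with 0 of 17 called (CDC14 at -0.88 ± 0.35, and HMLALPHA1 not above background on both slides), core and variant histones -0.02 with 0 of 11 called (HHF1 at -0.26 ± 0.21 and HHT2 at -0.22 ± 0.31), and NAD metabolism 0.01 with 1 higher (BNA1, 1.22 ± 0.04) and 17 not called. The bromodomain and coactivator subunits had a median of 0.03, with BDF2 itself as the 1 higher member and 37 not called. The sodium, potassium and calcium transport list had a median of -0.11 with 1 lower (the proton pump gene PMA2, -1.57 ± 0.18) and 27 not called, and trehalose and glycogen genes -0.12 with 0 of 19 called (TPS1 at -0.83 ± 0.18 and GSY1 at 0.81 ± 0.05). The glucose-repressed genes went both ways around a median of 0.04, with the hexose transporter genes HXT4 (1.48 ± 0.16), HXT6 (1.45 ± 0.02) and HXT7 (1.32 ± 0.05) higher, SIP4 (-1.18 ± 0.10) and HXT5 (-1.09 ± 0.02, named after its value was seen) lower, and 11 not called. The tricarboxylic acid and glyoxylate list had a median of 0.04 with 0 of 24 called (LPD1 at -1.02 ± 0.46 and CIT1 at 0.92 ± 0.07), and ribosome biogenesis factors 0.05 with 0 of 84 called (MAK16 at 0.77 ± 0.02 and NOP7 at 0.45 ± 0.20). Meiosis and sporulation genes had a median of 0.01, with 1 lower (SPS100, -2.00 ± 0.15) and 4 not called. The alpha-specific genes had a median of 0.11 with 0 of 2 called, and the plasmid and auxotrophic markers -0.12 with 0 higher, 2 lower (LEU2 and URA3) and 6 not called. None of the 28 mitochondrially encoded genes was above background on both slides, and their median was 0.01. The list percentiles describe this RNA pair only, since genes of a list can vary together between cultures.

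**Figure D3:**
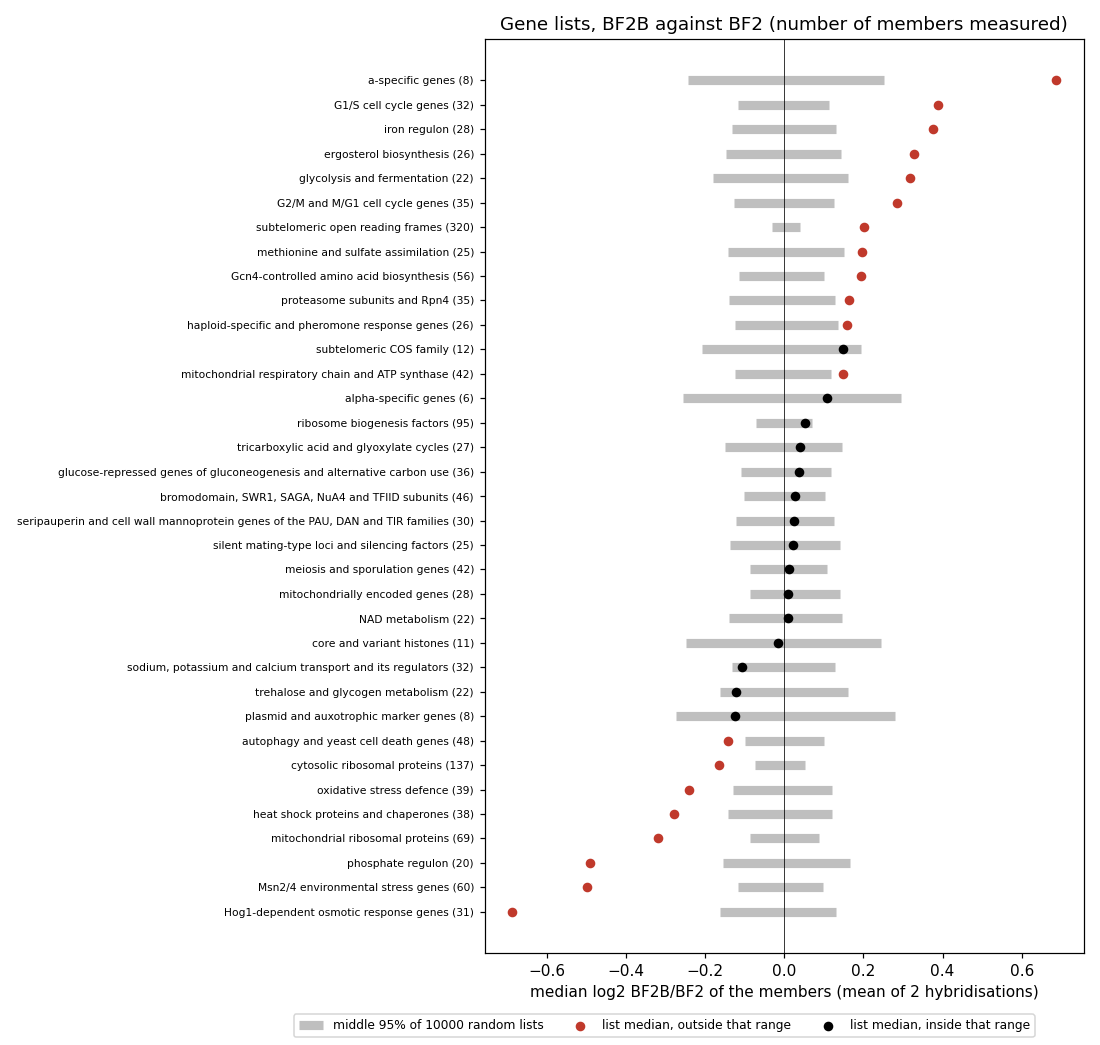
For each of the 35 gene lists (measured members in parentheses), the point is the median log2 ratio of BF2B to BF2 and the grey bar the middle 95% of medians of 10000 random lists matched on intensity. The medians run from -0.69 (Hog1-dependent genes) to 0.69 (a-specific genes), with 20 lists in red outside their bar.

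The comparison of the sample labelled BF2S with BF2 asked the same of the strain that also carries SIR2 H. Leading increases were RPL29, a ribosomal protein gene, with a log2 ratio of 5.95 ± 0.12, CAK1, a kinase gene, with 4.52 ± 0.24, and the autophagy gene ATG18 with 4.28 ± 0.22. YJL028W was at least 13.9-fold higher. The leading decreases were of genes not above background in the BF2S channel, so that only bounds can be given. YRO2 was at least 23.1-fold lower, the acetolactate synthase gene ILV2 at least 20.2-fold, YET1 at least 19.5-fold, the ATP synthase gene ATP1 at least 15.4-fold, HXT6 at least 15.1-fold, GAP1 at least 14.5-fold and HXT7 at least 14.2-fold. CWP1, MRH1, PST2, YFL068W and CLU1 were at least 12.2-fold, 11.7-fold, 6.97-fold, 6.31-fold and 6.25-fold lower. In all, 2351 of 5290 genes above background were called, 1023 higher and 1328 lower, a balance that turned on the filter (731 higher and 49 lower with both channels above background, 78 higher and 643 lower above the blank spots). Of the 1328 lower genes, 810 were not above background in the BF2S channel on either slide. The log2 ratios of the 2 hybridisations correlated at r = 0.952 across genes, with a median SD of 0.21.

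Many of these values rested on the within-slide correction. Under median centring REG1 went from 4.30 ± 1.04 to 1.68, HRP1 from 3.84 ± 0.08 to 1.03, QCR8 from 3.83 ± 0.05 to 0.93, RPL41B from 4.10 ± 1.01 to 0.72, CMR1 from 3.74 ± 1.17 to 1.61 and RPL29 from 5.95 to 2.65. RPS23A went from 4.26 ± 0.07 to -0.37 and YLR162W from 3.83 ± 0.30 to 0.07, whereas CAK1 kept 4.22, ATG18 3.66 and YLR255C 3.67. Of the 1023 higher genes, 51 fell below 0 under median centring, and 0 of the 1328 lower genes rose above it. The deposited value table gave 437 higher and 1036 lower, or 29.7% higher against 43.5%. With the marked spots left out, 1303 genes were called, 678 higher and 625 lower. Of the marker genes, URA3 stood at -0.20 ± 0.35, not called, but at -3.89 under median centring, and its signals were 3615 and 1778 units beside 48585 and 42263 units in BF2. LEU2, saturated in BF2, stood at -1.33 ± 0.43 and at -4.98 under median centring. LYS2 stood at -1.52 ± 0.15, while MET17 was at least 1.57-fold and CAN1 at least 2.07-fold lower.

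Among the lists, 6 lay above and 13 below the random range in the sample labelled BF2S, in whose channel blank spots were brighter than 96.0% of the genes. The random lists were matched on the mean intensity of both channels, not on the BF2 level alone. The 100 genes brightest on the BF2B slides had a median percentile of 63.4 and 58.5 in the BF2S channel, beside 99.2 in BF2. A list's ratio can therefore follow its BF2 level, and its place in the random range cannot be read as a response of that list. Stress genes lay low. Trehalose and glycogen genes had a median of -1.60 with 1 higher and 15 lower (GDB1 at least 13.1-fold). The Hog1-dependent genes had a median of -1.43 with 3 higher and 17 lower (PUT1 at least 12.5-fold), the Msn2/4 genes -1.29 with 6 higher and 33 lower (FMP45 at least 16.3-fold), and heat shock proteins -1.23 with 3 higher and 19 lower (KAR2 at least 12.1-fold and HSP82 at least 10.6-fold). Ion transport genes had a median of -1.16 with 2 higher and 14 lower (the proton pump gene PMA1 at least 23.1-fold). Core and variant histones had a median of -2.11 with 1 higher and 7 lower (HTA1 at -4.08 ± 0.30). The proteasome median was -1.14 with 1 higher and 17 lower (PRE4 at least 8.39-fold), and that of the Gcn4-controlled genes -1.09 with 4 higher and 25 lower (ILV3 at least 15.7-fold). The same count was 3 higher and 12 lower for the tricarboxylic acid list (median -1.10, CIT2 at least 8.47-fold), 4 and 17 for the respiratory chain (-0.99), 2 and 12 for ergosterol biosynthesis (-0.94), 0 and 11 for G2/M and M/G1 genes (-0.59) and 24 and 43 for cytosolic ribosomal proteins (-0.55). With genes at their bounds, the histone median was -1.38 and the respiratory chain median -0.52, and those of ion transport, ergosterol biosynthesis and G2/M and M/G1 genes were -0.31, -0.54 and -0.48. Bounds can only move values towards 0 and no random lists were redrawn at bounds, so these medians cannot be placed in a random range.

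Mitochondrial, meiotic and haploid-specific genes lay high in the sample labelled BF2S, beside the same bright blank spots and under the same limit of the matching. The counts of their members stand beside 44.4% of all genes above background that were called in this comparison. The mitochondrially encoded genes had a median of 1.65 over 28 members. Only 11 were above background, with 11 higher and 0 lower, BI3 among them at 1.77 ± 0.28. Meiosis and sporulation genes had a median of 1.35, and of 30 above background 20 were higher (MSH5, 2.34 ± 0.54, and SPO11, 1.81 ± 0.16) and 1 was lower (SPS100, -3.04 ± 0.02). Haploid-specific genes had a median of 1.05 with 7 higher and 5 lower of 18 above background. Subtelomeric open reading frames had 0.79 with 86 higher and 49 lower of 222, and 0.50 with genes at their bounds. The G1/S genes had 0.72 with 7 higher (SMC3, 1.92 ± 0.86) and 1 lower of 25. The glucose-repressed genes had a median of 0.81 with 10 higher and 9 lower, and a median of 0.00 with genes at their bounds. With the marked spots left out, the medians of the glucose-repressed and haploid-specific lists turned to -2.19 and -0.57. The former then lay below the random range, at percentile 0.07, and the latter inside it, at 30.3. Besides the haploid-specific list, 7 of the 19 lists outside the random range re-entered it with the marked spots left out, namely ion transport, heat shock proteins, the respiratory chain, ergosterol biosynthesis, meiosis, G1/S and mitochondrially encoded genes. In the value table ion transport, cytosolic ribosomal proteins, haploid-specific genes, histones and G1/S genes did so, and under median centring G2/M and M/G1 genes. The remaining 16 lists lay inside the random range, among them the silencing list (median 0.17, with 2 higher, SIR2 and ABF1, the latter named after its value was seen, and 3 lower), glycolysis (0.07), ribosome biogenesis (0.07), oxidative stress defence (-0.23), mitochondrial ribosomal proteins (-0.08) and the iron regulon (0.36).

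The sample labelled BF2S was compared with BF2B through their shared reference BF2, which asks what differs between strains that share BDF2 L but not SIR2 H. RPL29 was higher by a log2 difference of 7.20 ± 0.21, ATG18 by 5.43 ± 0.06 and CAK1 by 5.01 ± 0.33. Among decreases, the hexose transporter genes HXT6 and HXT7 were higher in BF2B than in BF2 and below background in the BF2S channel, as were the iron oxidase gene FET3, ITR1 and HXT4, so no fold can be read for them. The same holds for ILV2, MRH1, YFL068W, CWP1, PMA1, CLU1 and ILV3, which were not called in BF2B. Of the manipulated genes, BDF2, on a construct in both strains, stood at -0.95 ± 0.58, not called, and at -2.31 under median centring, and SIR2 and BDF1 were not above background on the BF2B slides, so neither could be called. Of the marker genes, LYS2 was lower at -1.67 ± 0.32, MET17 was called lower with no BF2S signal above background, and the others were not called. The uncalled LEU2 (1.15 ± 0.63, from spots saturated in BF2 on every slide) and URA3 (0.92 ± 0.44) turned to -2.67 and -2.84 under median centring. Altogether 1552 of 4314 genes were called, 277 higher and 1275 lower, with r = 0.911 between slide pairs and a median SD of 0.31. The number of higher genes over 2-fold in BF2S against BF2B depended on the processing, with 100 (beside 66 lower) with both channels above background, 141 in the value table, 172 under median centring, 516 and 539 on a single slide and 899 with no filter on dim spots. Of the 277 higher genes, 51 fell below 0 under median centring, among them the leading genes RPS23A (4.58 against -0.09), CPR1 (4.24 against -1.40), ALD3 (4.02 against -0.87), DET1 (3.98 against -0.51) and BMH1 (3.88 against -0.64). The other leading increases shrank as well, RPL41B from 4.59 ± 0.58 to 1.22, GYP7 from 3.73 ± 0.73 to 1.09, RPL28 from 3.65 ± 0.28 to 0.22, QCR8 from 3.54 ± 0.13 to 0.65 and RPL29 to 3.91, while ATG18 kept 4.81 and CAK1 4.73.

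Of the lists, 4 lay above and 6 below the random range in this comparison, again beside the bright blank spots of the BF2S channel. The same limit of the matching on intensity holds here. The mitochondrially encoded genes had a median difference of 1.63 with 0 of 28 above background on all slides. Meiosis genes had 1.19 with 0 higher and 1 lower of 5 above background, but 0.14 in the deposited value table and -1.54 with the marked spots left out, and mitochondrial ribosomal proteins 0.31 with 6 higher (MRPS5, 3.04 ± 0.45) and 8 lower. Cytosolic ribosomal proteins stood above their random lists at a median of -0.40, with 24 higher and 37 lower, but below random lists not matched on intensity. The 6 low lists were the COS family (-1.34, with 1 higher and 5 lower), the respiratory chain (-1.29, with 2 and 16), ergosterol biosynthesis (-1.27, with 1 and 15), G2/M and M/G1 genes (-0.82, with 0 and 14), ion transport (-0.78, with 1 and 12) and the iron regulon (-0.78, with 1 and 10). The Hog1-dependent genes lay inside the random range at -0.94. Of these 10 lists, ion transport, the respiratory chain, COS and G2/M lists re-entered the range under median centring and, with the iron and mitochondrially encoded lists, in the value table. With the marked spots left out, the ion transport, respiratory chain, mitochondrial ribosomal, iron, ergosterol and COS lists did so. On a single slide pair, ion transport did so on either and the iron regulon on the second, where its median was -0.27.

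Genes moving in the same direction in BF2B and in the sample labelled BF2S numbered 43 of the 4314 above background in both, 4 higher and 39 lower (2 with both channels above background, 66 and 69 on a single slide). The 4, named after their values were seen, were CUP1-2, IRC8, YGR067C and YHB1. Independent lists of these sizes would share 4.26 and 23.0 genes, and 2.02 shared calls arose on average in 100 simulations with no effect and a common BF2 sample. A further 30 genes moved in opposite directions. Of these, 25 were higher in BF2B and lower in the sample labelled BF2S, and 5 the reverse, where independent lists would share 18.7 and 5.23. Genes called in BF2B in either direction were thus more frequent among the BF2S decreases than independent lists would give. Across genes the log2 ratios of both comparisons correlated at a Pearson r of 0.057 and a Spearman rho of 0.054, with a covariance of 0.036. The simulations with a common reference gave an r of 0.368 and a covariance of 0.072. The simulation assumed that all 3 RNA samples vary alike, with a sample SD of 0.268. This did not hold, since the SD of log2 ratios across genes was 1.53 in the sample labelled BF2S and 0.44 in BF2B. The simulated r and shared calls therefore give no baseline for the observed ones, and the simulated covariance rests on the assumed SD. With 1 BF2 RNA the control could not be split, so part of the shared calls may come from it.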

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

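The tests on probe positions and on the brightest genes were chosen after the weak correlation of the BF2S channel had been seen. Spots without a yeast probe, which the comparisons do not use, gave signal on the BF2S slides. Blank spots had medians of 6049.25 and 5325 units in the BF2S channel and 1708.5 and 1767.5 units in the BF2 channel. Spots of 50%DMSO had 7158.5 and 7425.75 units in the BF2S channel and 2430.75 and 2058.75 units in the BF2 channel. On the BF2B slides blank spots had 29 to 110 units.

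The pattern weighed is that the BF2S channel does not follow the other channels, least those of the BF2B slides (r with BF2B 0.113 to 0.176) and less so BF2 on its own slides (r 0.405 to 0.482). Wrong probe positions on its slides are argued against by the BF2 signals of the same slides, which correlated with those of the BF2B slides at 0.868 or more, and background correction by a Spearman rho of at most 0.138 between plain spot medians of BF2S and BF2B. The spread of log2 ratios of the cytosolic ribosomal protein genes was 9.38 times that in BF2B. This cannot decide on a coordinated change of these genes, because the whole channel was spread wider. Over all genes above background the SD was 1.53, beside 0.44 in BF2B. Little yeast messenger RNA with much non-specific signal stays open, since the 100 genes brightest on the BF2B slides had a median percentile of 63.4 and 58.5 in the BF2S channel, beside 99.2 in the BF2 channel. Control spots were not part of a planned test, and those named ACT1, SSA4, UB14 and RPL32 were mixed. In the BF2S channel ACT1 spots lay above 15.0% and 10.4% of the genes, beside 92.1% and 91.9% in BF2. SSA4 spots lay above 17.0% and 10.3%, beside 89.7% and 88.5%. UB14 spots lay above 63.3% and 50.7%, beside 93.5% and 93.1%, and RPL32 spots above 76.7% and 82.8%, beside 81.3% on both slides. Control spots named Y1, Y2, Y3, Y5 and Y7 lay above at least 99.9% of the genes in the BF2S channel on both slides. In BF2 on the first slide they lay above 94.4%, 91.8%, 60.7%, 30.8% and 33.5%. Y4 and Y8 spots also lay higher in the BF2S channel than in BF2. Y6 spots lay lower, above 66.2% beside 74.9% on the first slide. A different sample behind the label also stays open and was not tested.

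Several genes named in the report moved in opposite directions in BF2B and in the sample labelled BF2S on every slide after the loess correction, and these differences were not tested. The differences in log2 ratio were 7.20 for RPL29, 5.43 for ATG18 and 3.98 for DET1, and -3.48 for SAM2, -3.38 for LEU1, -3.15 for TIP1 and -2.66 for DLD3, the latter 4 with a BF2S signal above background on the first slide only. For DET1 the opposite movement rested on loess alone, since its difference was -0.51 under median centring and -0.55 in the deposited value table, and that of RPL29 fell to 3.91 and 4.01. In the remaining genes the BF2S signal was not above background on either slide, so the fitted values of -6.91 for HXT6, -6.89 for HXT7, -5.99 for ITR1, -5.89 for FET3, -5.66 for HXT4, -4.65 for SVS1, -4.26 for ERG3, -3.78 for SNZ1, -3.34 for ERG5 and -2.53 for SNO1 give no fold. Among lists whose medians had opposite signs in BF2B and the sample labelled BF2S, the median of the per-gene differences was -1.29 for the respiratory chain, -1.27 for ergosterol biosynthesis and -0.82 for G2/M and M/G1 genes, each below the random range. Such medians of the proteasome (-1.38, percentile 4.33) and Gcn4-controlled genes (-1.08, percentile 10.8) lay inside the random range. The limit of the matching on intensity given above holds for all of these lists.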

How the results depend on the processing

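The tests with spots marked -100 left out and with genes above the blank spots were chosen after the data were seen. No list of BF2B against BF2 outside its random range, and no called gene among those picked by the rule for names, changed sign under any alternative, while its other called genes were not followed one by one. Uncalled genes and lists inside the range did change sign, such as LYS2 from 0.14 to -0.04 in the deposited value table. Its 139 calls became 411 at 1.5-fold, 30 at 3-fold and 224 to 227 on a single slide (without replicate 1 or 2), through the threshold or the fewer slides, and stayed within 1.5 times otherwise. The 2351 calls of BF2S against BF2 became 1473 in the deposited value table, 1303 with marked spots left out, 780 with both channels above background (731 higher, 49 lower), 721 above the blank spots (78 higher, 643 lower) and 1102 at 3-fold. The 1552 of BF2S against BF2B became 704 with marked spots left out, 166 with both channels above background (100 higher, 66 lower), 691 above the blank spots and 940 at 3-fold. The 43 shared calls became 28 with marked spots left out, 2 with both channels above background, 141 at 1.5-fold, 9 at 3-fold and 66 to 69 on a single slide. The filters test fewer or other genes by construction, while the thresholds test the same genes and change only the size that a call must reach. The correlation of 0.057 became 0.122 in the value table and -0.020 with both channels above background, and the cause was not tested. Median centring differs from the main processing only in replacing loess, so a sign that turned under it rested on loess. Some log2 ratios of named genes called under loess changed sign under median centring and in the value table. Against BF2 these were CPR1 (-1.88 and -1.99), PGK1 (-2.63 and -2.78), RPS23A (-0.37 and -0.41) and, in the value table only, YLR162W (-0.0024). Against BF2B they were ALD3 (-0.87 and -0.85), BMH1 (-0.64 and -0.56), CPR1 (-1.40 and -1.46), DET1 (-0.51 and -0.55), PGK1 (-2.92 and -2.96), RPS23A (-0.091 and -0.056) and RTN2 (-1.35 and -1.31). Uncalled genes changed sign too, among them BDF2 against BF2 (from 0.65 to -0.73 and -0.88) and, against BF2B, LEU2 (from 1.15 to -2.67 and -2.99, with spots saturated in BF2 on every slide) and URA3 (from 0.92 to -2.84 and -2.88). The meiosis median of BF2S against BF2B became 0.14 in the value table and -1.54 with marked spots left out, where the glucose-repressed and haploid-specific medians of BF2S against BF2 became -2.19 and -0.57, and the cause was not tested. The cytosolic ribosomal protein median of BF2S against BF2B, -0.40, lay below its random lists when these were not matched on intensity. Lists with no measured member after marked spots were left out have no value there. No paired analysis was possible because the result comes from no test and the replicate number marks the dye orientation. Signal over background limits the sample labelled BF2S most, with 35.8% of gene spots above background on its second slide.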

Other observations

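The inositol and nitrogen lists below were written, with their predictions, after the leading genes had been seen and before the values of the further members were, and the probe YDL071C was chosen after its value was seen. Phospholipid genes lay higher in BF2B beyond INO1. Of 22 further genes listed under the inositol-sensitive promoter element, among them regulators, a transporter and fatty acid synthesis genes, all were above background and 1 was called higher (PSD1, 1.33), and EPT1 stood at 1.03, HNM1 at 0.99, CPT1 at 0.87, OPI3 at 0.80 and DPP1 at -0.65. Their median of 0.42 lay at percentile 100 of random lists. As a hypothesis, shared control through the inositol-sensitive promoter element could link them to INO1, and the test was met, at percentile 100 under every alternative.

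Nitrogen genes lay slightly lower in BF2B beyond MEP2, GAP1 and DAL80. Of 24 further genes under nitrogen catabolite repression, 13 were above background and 1 was called lower (the activator gene GAT1, -1.21). Their median of -0.14 lay at percentile 1.77 of random lists, at the edge of the random range. Shared control through nitrogen catabolite repression is a hypothesis that this value could fit, while no other culture was measured.

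The probe for YDL071C, an open reading frame whose systematic name is next to that of BDF2 (YDL070W), was at least 3.07-fold higher in BF2B. Its signals were 937.3 and 1337 units in BF2B and were not above background in BF2. On the BF2S slides it was not above background in either channel.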
